A study of Daphnia pulex with 24 samples.

How the data were processed

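The samples were whole-body Daphnia pulex, a freshwater crustacean, kept under 8 treatments that crossed high or low dietary phosphorus, high or low food quantity, and the absence or presence of arsenic at 0.132 mg/L. Polyadenylated RNA was selected and made into libraries with the Nextera DNA Flex kit, per the labels' protocols. The labels describe 24 libraries, and 23 of them had a column in the count table used here; 1 control library was not analysed here. The deposited values are estimated counts per gene, and the tools named, per the submitters' processing notes, were Trimmomatic 0.27 and Salmon 1.9.0. How transcript estimates were combined per gene, the genome build, and whether strand was used are not given in the sources used here. Of the deposited estimated counts, 10.8% had decimals, and all were rounded to whole numbers before testing. The count table held 19311 genes, of which 15204 had a protein product in the annotation table the authors deposited, and 4014 of those products were uncharacterized. All 19311 identifiers were found in the RefSeq gene table of assembly ASM2113471v1, and the coding spans of all 15294 annotated loci lay inside the matching RefSeq gene. Positions are the coding spans as deposited.

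Libraries were compared in all 253 pairs before any were averaged. A biological coefficient of variation (BCV) was estimated with edgeR over genes with a summed count of at least 20, and a chi-square per degree of freedom over genes with an expected count of at least 5. Counts of 2 libraries of 1 group with a BCV under 0.2 were summed and counted as 1 unit. The design fixed before the data were examined counted every library, so the summing was decided after seeing the data, and the fit with every library counted is given beside it. Libraries 1 and 14 were left out because both are labelled replicate 1 of arsenic alone, a group with 4 labelled libraries where the series design gives 3, while low food alone has 2. This left 21 libraries in 15 units. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these units.

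One model with 1 coefficient per group was fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr by group), with 7 residual degrees of freedom over 12945 genes. Groups of 1 unit were assumed to vary like the others. Each of 17 contrasts was adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of F. Averaged comparisons weight the 4 strata equally. A set of 30 gene lists was fixed by product name before the data were examined. The lists were tested with limma 3.58.1 camera with a preset inter-gene correlation of 0.01 and again with an estimated one. The following 2 tests were added after seeing the data: limma on 1 score per list and unit (the mean of centred log2 CPM, prior count 2), and a two-sided exact permutation of those scores for the averaged comparisons (SciPy 1.17.1). The permutation shuffled all units without regard to the other factors. It tested the plain difference between the means of units with and without the factor, not the equally weighted average over strata. Named genes follow a rule fixed before the data were examined: up to 10 genes each way with the largest fold change past the threshold, average log2 CPM of at least 1, a known product, and the same direction in every stratum or no overlap between groups, with 3 each way for secondary comparisons and up to 4 members per list. No gene passed the threshold in the fit of units, so the rule was applied to the fit that counts every library, and values are from the fit of units. A fold against a group without counts was computed against a floor of 3 counts over the group, which covers counting error only.

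Alternatives were DESeq2 1.42.0, median-ratio scaling, no filter, each library left out, libraries 1 and 14 kept, and the replicate number as a block. Further alternatives were chosen after seeing the data: every library counted, libraries 46 or 43 and 50 left out, each summed pair left out, libraries 43 and 50 averaged into 1 unit for the low food and low phosphorus averages, each unit left out of the list scores, and an additive fit. The steps were tested on simulated data with 200 changed genes. For low food averaged over the other factors, over 12537 genes, edgeR called 58 of 66 genes changed by 4 on the log2 scale, 25 of 67 changed by 2 and 4 of 67 changed by 1, with 10 false calls. DESeq2 called 64, 49 and 13 of them with 73 false calls. For arsenic alone against the control, with 1 unit in each group and 12460 genes, edgeR called 0 of the changed genes at every size, and DESeq2 called 25 of 66 at 4, 6 of 67 at 2 and 0 of 67 at 1, with 67 false calls. Genes of multigene families, such as trypsins, vitellogenins and cuticle proteins, are uncertain where reads could be shared between copies.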

Results

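Whole-body transcripts of Daphnia pulex were counted under 8 combinations of dietary phosphorus, food quantity and arsenic, with high phosphorus, high food and no arsenic as the control. The question in the series title was how nutrition and arsenic act alone and together. Library totals ran from 200189 counts in library 46 (low food alone) to 2321535 in library 1 (arsenic alone). The most abundant gene, LOC124194813 (NADH-ubiquinone oxidoreductase chain 1-like), took 1.87% to 11% of a library's counts.

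Of 253 pairs of libraries, 7 were near-identical, with a BCV of 0.0312 to 0.109 and 1.2 to 3.45 times counting variance. The other 246 pairs had a BCV of 0.350 to 0.832 and at least 12.4 times counting variance. Within groups, 4 near-identical pairs had 1.2 to 1.59 times counting variance, while libraries 28 and 33 (arsenic with low phosphorus) had 2.55 times and libraries 35 and 38 (arsenic alone) 3.45 times. All 6 exceeded counting variance alone, and each was counted as 1 sample, here called a unit. The remaining pair joined library 43 (low phosphorus and low food) with library 50 (the same diet with arsenic) at a BCV of 0.0356, and both were kept as labelled. The labels do not say whether libraries came from separate cultures, so every p-value here measures only the spread between these units. The 15 units left 1 unit in the control, 1 in arsenic alone, 3 in the group with all stressors and 2 in each other group. The 17 same-group pairs that were not near-identical, those with libraries 1 and 14 included, had a median BCV of 0.648. It was 0.604 for other pairs from different groups. The closest same-group pairs were removed before this median was taken, so the 2 values do not compare likeness within and between groups.

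**Figure D1:**
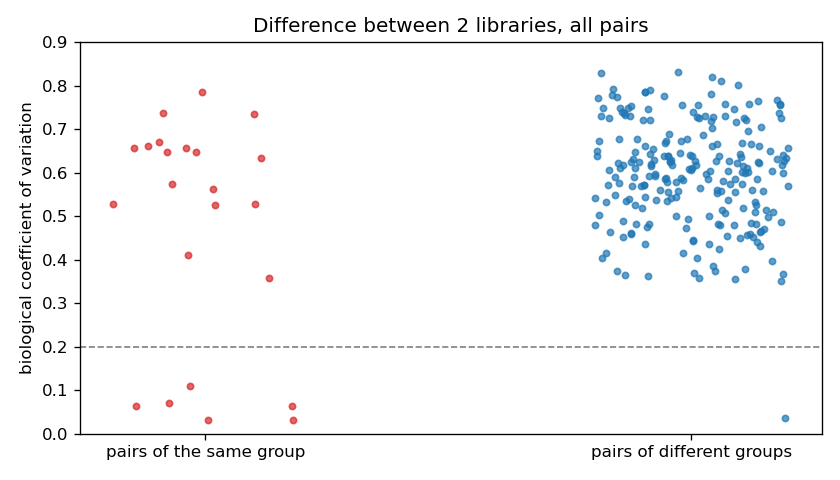
Biological coefficient of variation (vertical axis, no unit) of each of the 253 pairs of libraries, for pairs of the same group in red and of different groups in blue; each point is 1 pair, spread sideways at random, and the dashed line is at 0.2. The 7 pairs under the line sit at 0.0312 to 0.109, and all others at 0.350 or above.

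Under low food, averaged over phosphorus and arsenic, 15 of the 33 vitellogenin and apolipoprotein genes, among them yolk protein genes, were lower and 18 higher. LOC124209456 (vitellogenin-like, chromosome 12, 2465535 to 2473270) averaged 1.97 ± 1.17 CPM (SD, n = 9) under low food and 99.3 ± 124 CPM (SD, n = 6) under high food, and no low-food unit, at most 3.45 CPM, reached the lowest high-food unit at 6.21 CPM. The low-food mean was 1.79 ± 1.12 CPM (SD, n = 8) with the near-identical libraries 43 and 50, which n = 9 counts separately here and below, taken as 1 unit. The log2 fold change of LOC124209456 was -5.50 ± 0.81 (SE), with an edgeR p of 4.4e-05 and an adjusted p of 0.193. Neighbouring genes on chromosome 6, LOC124195932 (vitellogenin-3-like, 4429264 to 4436531), LOC124195930 (vitellogenin-like, 4419037 to 4426308) and LOC124195931 (vitellogenin-like, 4457472 to 4465050), had log2 fold changes of -8.56 ± 1.83, -6.58 ± 1.82 and -5.21 ± 0.92 (SE). Levels differed widely within groups: LOC124195930 stood at 5.88 CPM in one unit of low food with arsenic and at 4260.0 CPM in the other. LOC124199287 (vitellogenin-1-like) was higher under low food, at 98.9 ± 81.4 CPM (SD, n = 9) against 19.5 ± 11.9 CPM (SD, n = 6).

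**Figure D2:**
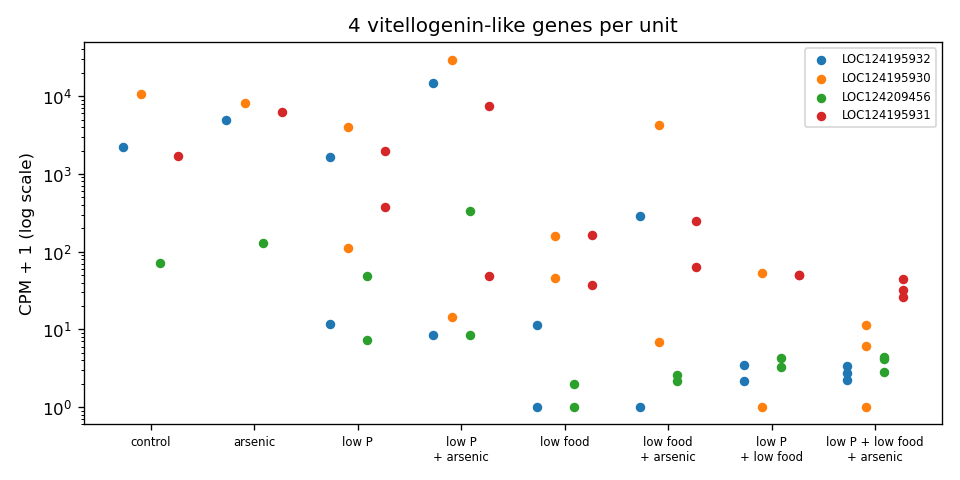
CPM plus 1 on a log axis for 4 vitellogenin-like genes in each of the 15 units, by treatment group; each point is 1 unit and each colour 1 gene. LOC124209456 lies at or below 3.45 CPM in all low-food units and at or above 6.21 CPM in all high-food units, while the other genes overlap.

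All 41 members of the DNA replication and cell cycle list had negative log2 fold changes under low food, with a median of -1.16. The mitotic cyclins LOC124204863 (cyclin-A-like) and LOC124197283 (cyclin-B-like), which drive entry into mitosis, stood at -3.11 ± 0.49 and -3.18 ± 0.62 (SE), and LOC124190390 (geminin-like), which limits DNA replication to one round, at -2.78 ± 0.55 (SE). Of 20 histone genes 18 were lower, with LOC124192818 (histone H3) at -3.80 ± 0.83 (SE). The list score difference was -1.27 ± 0.35 (SE) for DNA replication and -0.71 ± 0.18 (SE) for histones, each with a limma adjusted p of 0.068, and -0.90 ± 0.28 (SE) for the 33 vitellogenin and apolipoprotein genes, with a limma adjusted p of 0.083. The exact permutation p, for the plain difference of unit means, was 0.0140, 0.00519 and 0.00959 in that order, each 0.140 after adjustment over 30 lists. With libraries 43 and 50 as 1 unit the exact permutation p was 0.0220, 0.00799 and 0.0160, each 0.220 after adjustment. The vitellogenin list had a median log2 fold change of 0.07 and a mean of -0.49, so the signs differ. Means for DNA replication and histones were -1.29 and -0.86. Scores may also depend on depth. Libraries 46 and 50, the units with the fewest counts, are both low food. Library 50 scored below its near-identical library 43 on every list but vitellogenins (-1.28 against -0.756 for DNA replication). Under low food alone every list score difference was negative. It was -0.50 for digestive peptidases, whose mean log2 fold change was 0.63. An effect of depth was not tested. Camera with the preset correlation called 9 lists, among them DNA replication (adjusted p 2.09e-16), ribosome biogenesis (0.00198, lower) and neural and eye markers (9.29e-10, higher, 66 of 75 members), and with an estimated correlation the adjusted p was at least 0.818 for every list.

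**Figure D3:**
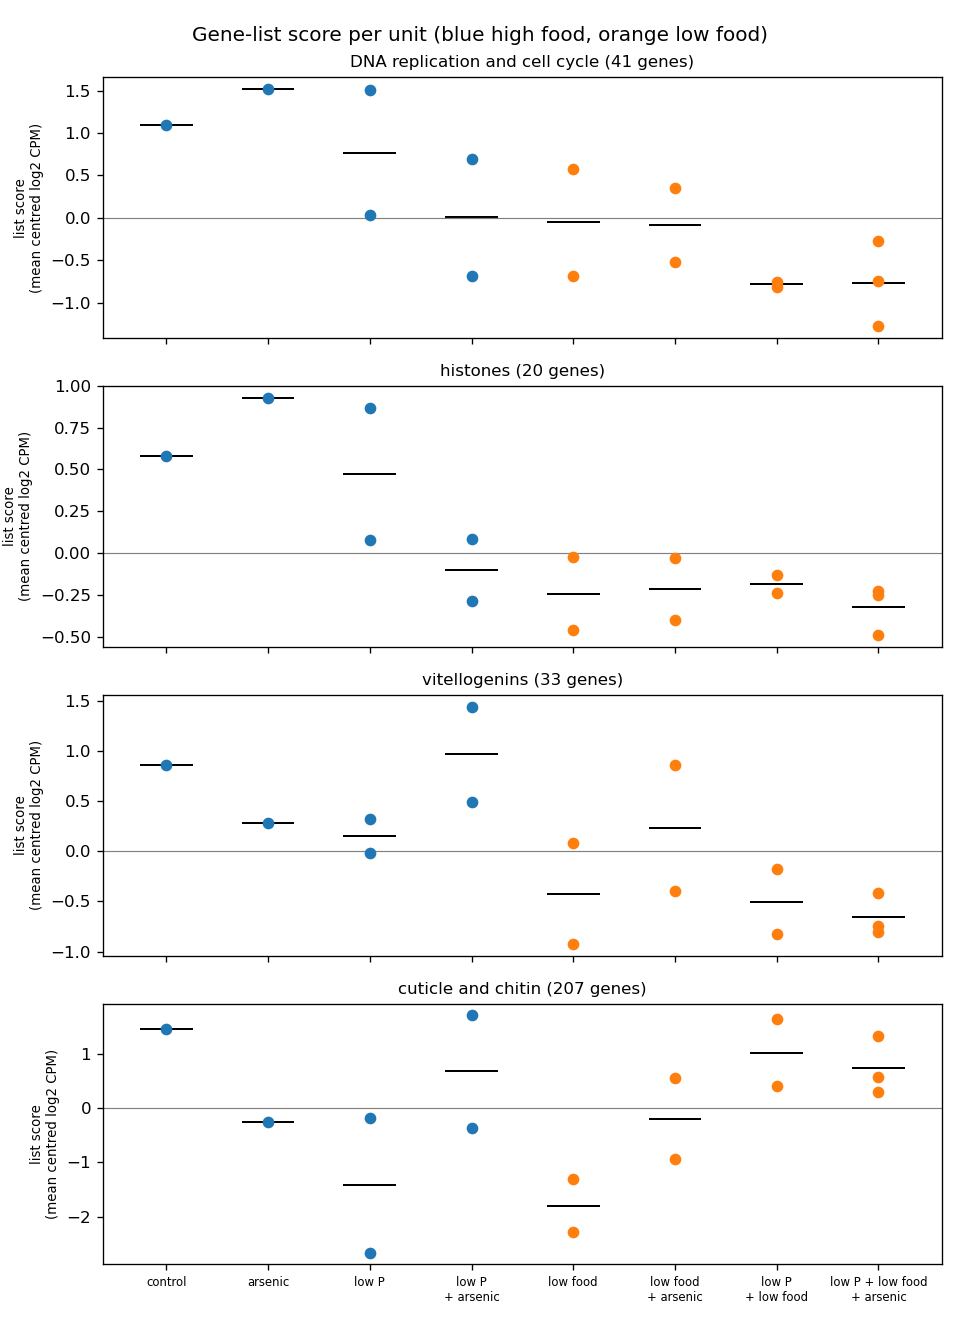
List score (mean centred log2 CPM, vertical axes) of 4 gene lists in each of the 15 units by treatment group, high food in blue and low food in orange; points are units and black bars are group means. DNA replication scores run from -1.28 to 0.576 in low-food units and from -0.683 to 1.52 in high-food units, so the ranges overlap.

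In edgeR 0 of 12945 genes passed for low food, with 1287 at an unadjusted p under 0.05 where 647 would be expected by chance. That count was 794 without libraries 43 and 50, 778 without the pair of libraries 28 and 33, and 2038 without the pair of 31 and 52. DESeq2 called 77 higher and 105 lower, and edgeR with every library counted called 249 higher and 393 lower. Adjusted over the list alone, 14 DNA replication genes and 4 vitellogenin genes were lower. The 647 genes expected by chance at an unadjusted p under 0.05 hold for every comparison below. Counts fell short of 647 for low phosphorus alone, low food alone, arsenic with low phosphorus and arsenic with low food. They also did for arsenic within each stressed diet, arsenic averaged and arsenic by food. Arsenic alone and phosphorus by food stood just above it.

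Under low phosphorus, averaged over food and arsenic, 24 of 32 fatty acid synthesis genes were higher and 40 of 41 DNA replication genes lower. The exact permutation p of the list scores was 0.0915 and 0.184, each 0.580 after adjustment. LOC124206050 (serine protease 41-like) averaged 84.7 ± 150.0 CPM (SD, n = 9) under low phosphorus and 616 ± 740.0 CPM (SD, n = 6) under high phosphorus. Its log2 fold change was -6.16 ± 1.5 (SE), well beyond the ratio of these means. Fold changes of averaged comparisons weight the strata equally on the log scale, while the CPM means pool all units. LOC124204709 (trypsin alpha-4-like) stood at -5.48 ± 1.09 (SE), while 90 of the 148 digestive peptidase genes were higher, with a median of 0.35 and a limma score difference of 0.12 ± 0.35 (SE). With 1 unit left out at a time that difference ran from -0.13 (without library 46) to 0.37 (without library 36), and it was also below 0 without the pair of 31 and 52 (-0.04). LOC124203173 (sulfotransferase 1B1-like) averaged 246 ± 164 CPM (SD, n = 9) against 20.6 ± 28.5 CPM (SD, n = 6), with a log2 fold change of 4.14 ± 1.24 (SE). The fatty acid synthesis gene LOC124193977 (fatty acyl-CoA reductase) stood at 2.38 ± 0.58 (SE) and LOC124197283 (cyclin-B-like) at -2.62 ± 0.61 (SE), and 66 of 68 mitochondrial ribosomal protein genes were lower, with a median of -0.49. Phosphate transport, with 9 genes, had a median log2 fold change of -0.12 and a limma score difference of -0.07 ± 0.24 (SE), or -0.21 without library 46 and 0.07 without library 36. In edgeR 0 genes passed (lowest adjusted p 0.55), with 1122 at an unadjusted p under 0.05, and DESeq2 called 101 higher and 33 lower. The count of 1122 was 619 without libraries 43 and 50, 675 without library 48, 721 without the pair of libraries 20 and 29, and 1824 without library 3. With every library counted edgeR called 338 higher and 223 lower. Camera with the preset correlation called 9 lists, and the lowest adjusted p with an estimated correlation was 0.842.

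Arsenic averaged over the 4 diets gave the fewest differences of the 3 factors at an unadjusted p. Near-identical libraries 43 (no arsenic) and 50 (arsenic) stand on opposite sides within low phosphorus and low food. Part of any small difference within that diet, and so in the average, may come from this pair. The list named arsenic methylation and efflux is broader than its name. Its product names also took in aquaporins and transporters of ATP-binding cassette sub-family C. The 13 genes of this list had a median log2 fold change of -0.10 and a limma score difference of -0.12 ± 0.16 (SE, n = 15 units). This difference was -0.20 without library 49, -0.07 without the pair of 20 and 29 and -0.04 without the pair of 31 and 52. The value of -0.12 averages differences of both signs, -0.83 ± 0.42 (SE) under high phosphorus and high food, 0.46 ± 0.30 under low phosphorus, 0.32 ± 0.30 under low food and -0.43 ± 0.27 under both. The second was 0.13 without library 49 and 0.79 without the pair of 31 and 52, and the third 0.10 without library 3, 0.20 without library 46 and 0.54 without the pair of 20 and 29. The 68 glutathione and thioredoxin genes had a median of -0.05, a mean of -0.01 and a score difference of 0.03 ± 0.18 (SE), so the signs differ. With 1 unit left out at a time it ran from -0.08 (without library 46) to 0.13 (without library 36), and was also below 0 without library 43, library 49, the pair of 20 and 29 or the pair of 28 and 33. The 28 metal binding genes had a median of -0.04 and a score difference of 0.17 ± 0.25 (SE), which was -0.02 without library 46, 0.10 without library 49 and 0.37 without library 36. The 49 heat shock genes had a score difference of 0.10 ± 0.21 (SE), which ran from -0.02 (without library 46) to 0.21 (without library 36) and was also below 0 without the pair of 31 and 52 (-0.01). For arsenic averaged over diets edgeR called 0 genes, 209 stood at an unadjusted p under 0.05, DESeq2 called 6 higher and 6 lower, and edgeR with every library counted called 0. The count of 209 was 138 without the pair of libraries 37 and 51, 328 without library 46, 349 without the pair of 31 and 52, 355 without library 36 and 391 without library 49. Of 207 cuticle genes 150 were higher, with a camera adjusted p of 0.0235, and 0.996 with an estimated correlation. With the preset correlation the adjusted p was 0.868 without libraries 43 and 50 and 4.05e-08 with libraries 1 and 14 kept, and the mean log2 fold change of 0.67 was 1.12 with those kept, 0.06 without the pair of libraries 28 and 33, 0.07 without the pair of 20 and 29, 1.32 without library 36 and 1.43 without the pair of 31 and 52.

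Arsenic alone was compared with the control with 1 unit each. LOC124197781 (integumentary mucin C.1-like) stood at 557 CPM with arsenic and had no counts in the control, at least 754-fold higher against the floor of 3 counts over the group. LOC124203650 (brachyurin-like), a digestive protease, stood at 259 CPM in the control and had no counts with arsenic, at least 306-fold lower. Of 148 digestive peptidase genes 106 were lower, with a median log2 fold change of -1.12, and LOC124190370 (alpha-amylase 1-like) stood at -6.28 ± 2.31 (SE). LOC124197781 was also at 339 CPM in one unit of low phosphorus alone and at most 6.88 CPM in every unit outside these groups. In edgeR 0 genes passed (lowest adjusted p 0.934), 683 stood at an unadjusted p under 0.05, DESeq2 called 5 higher and 20 lower, and with every library counted edgeR called 122 higher and 427 lower. In simulated data of this comparison edgeR called 0 of 66 genes changed by 4 on the log2 scale, and DESeq2 called 25 of 66 with 67 false calls. With libraries 1 and 14 kept as labelled, 128 genes stood at an unadjusted p under 0.05, and the mean log2 fold change of the digestive peptidase list turned from -1.99 to 0.60. Camera called 11 lists, and the lowest adjusted p with an estimated correlation was 0.784.

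Under low phosphorus alone, 176 of 207 cuticle and chitin genes were lower than in the control, with a median log2 fold change of -2.38, and LOC124193563 (cuticle protein 18.7-like) stood at 148 CPM in the control and had no counts under low phosphorus, at least 183-fold lower. The paired genes LOC124190750 and LOC124190749 (piwi-like protein Siwi), which silence transposons in the germ line, stood at 3.86 ± 1.18 and 3.55 ± 1.05 (SE), and LOC124195545 (apterous-like), a homeobox regulator, at 2.67 ± 0.66 (SE). The cuticle list had a camera adjusted p of 2.46e-23, and 0.911 with an estimated correlation. No gene passed in edgeR (0 of 12945), 634 stood at an unadjusted p under 0.05, DESeq2 called 3 higher and 9 lower, and with every library counted edgeR called 21 higher and 64 lower. Without library 49 the count at an unadjusted p was 288, and without the pair of libraries 31 and 52 it was 1421 and the mean log2 fold change of cuticle genes was -5.83, against -2.74 with all units.

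Under low food alone, 157 of 207 cuticle genes were lower than in the control, with a median log2 fold change of -2.35. LOC124194157 (FTZ-F1-like), a nuclear receptor of the moulting cascade, stood at 369 CPM in the control and at 29.7 and 5.02 CPM under low food, a log2 fold change of -4.23 ± 0.85 (SE). The value of 5.02 CPM is at the lowest level measurable in library 46, which held 200189 counts. The cuticle list had a camera adjusted p of 1.69e-18, and 0.908 with an estimated correlation. Oxidative phosphorylation genes had a mean log2 fold change of 0.13, while the score difference was -0.01 ± 0.61 (SE), or -0.27 without library 36 and 0.25 without library 46. Low food alone gave 0 genes in edgeR, 389 stood at an unadjusted p under 0.05, DESeq2 called 1 higher and 17 lower, and with every library counted edgeR called 2 higher and 3 lower. Without library 36 the count at an unadjusted p was 737 and the mean log2 fold change of cuticle genes was -5.92, against -3.25 with it. The cuticle values of these single-stressor comparisons share 1 control unit, so part of their likeness may come from it.

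The groups with combined stressors were each compared with the control. Of 41 DNA replication genes 40 were lower under low phosphorus with low food (median -1.77), 39 under all stressors (-1.45), 36 under arsenic with low food (-0.86) and 37 under arsenic with low phosphorus (-0.68). The score differences were -1.88 ± 0.79, -1.86 ± 0.74, -1.17 ± 0.79 and -1.08 ± 0.79 (SE) in that order, with limma adjusted p of 0.77, 0.389, 0.935 and 0.992. The third was -0.73 without library 3, and the fourth -0.40 without library 48 and -1.77 without the pair of 28 and 33. The units of arsenic with low food scored 0.355 and -0.521 and those of arsenic with low phosphorus 0.691 and -0.683, against 1.09 in the control. These comparisons share that 1 control unit, whose score was exceeded by 2 of the 15 units, at 1.52 and 1.51, so part of their likeness may come from it. LOC124190940 (complement C1q tumor necrosis factor-related protein 4-like) stood at 114 and 293 CPM under low phosphorus with low food, at 55.8 to 295 CPM with arsenic added, and at 0.739 CPM in the control. Near-identical libraries 43 and 50 stand in low phosphorus with low food and in all stressors, so values of these groups are not independent. The same holds for their DNA replication scores. Low phosphorus with low food gave 1016 genes at an unadjusted p under 0.05, all stressors 1052, arsenic with low food 469 and arsenic with low phosphorus 249, and 0 passed in edgeR in each. Without libraries 43 and 50 the first count was 435 and the second 667, and without library 43 the first was 495. The third was 249 without library 3 and 1044 without the pair of libraries 20 and 29, and the fourth 103 without library 48 and 475 without the pair of 28 and 33. DESeq2 called 20, 71, 2 and 1 in the order of the groups, and edgeR with every library counted called 702, 603, 87 and 0.

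Arsenic was also compared within each stressed diet. Within low phosphorus and high food, 186 of 207 cuticle genes were higher, with a median log2 fold change of 2.74 and a score difference of 2.10 ± 0.91 (SE, limma adjusted p 0.539), and LOC124205283 (procathepsin L-like) stood at 3.05 ± 0.74 (SE). This score difference was 0.86 without library 49, 1.06 without the pair of libraries 28 and 33, and 3.33 without the pair of 31 and 52. The mean log2 fold change of 2.62 was 0.20 without the pair of libraries 28 and 33 and 5.70 without the pair of 31 and 52. Within low food, cuticle genes had a median of 1.2 and a mean of 2.35, which was -0.04 without the pair of libraries 20 and 29 and 4.99 without library 36, and within low phosphorus and low food -0.35. Within these diets edgeR called 0 genes, and 617, 198 and 81 stood at an unadjusted p under 0.05. The third comparison sets library 43 against the near-identical library 50, so part of its small count may come from this pair. The count of 81 was 132 without library 50. DESeq2 called 12, 30 and 2, and edgeR with every library counted called 1, 0 and 0.

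The interaction terms tested whether arsenic, phosphorus and food acted differently together. For phosphorus by food, LOC124201024 (acidic phospholipase A2 D-like) stood at 4.24 ± 0.68 and LOC124194157 (FTZ-F1-like) at 3.81 ± 0.75 (SE), each with an edgeR adjusted p of 0.969. Of 148 digestive peptidase genes 131 had a negative phosphorus by food term, with a median of -2.21 and a camera adjusted p of 1.42e-11, and the adjusted p was 0.704 with an estimated correlation. The mean of this list, -2.50, was -0.66 without library 36 and -1.15 with libraries 1 and 14 kept. For arsenic by phosphorus, LOC124205283 (procathepsin L-like) stood at 3.67 ± 0.80 (SE), with an edgeR adjusted p of 0.842. For the term of all 3 factors, LOC124198704 (torso-like), with 1 count under low food alone, stood at -9.76 ± 1.59 (SE, edgeR adjusted p 0.654), and the cuticle score difference was -5.71 ± 2.0 (SE, limma adjusted p 0.162). In edgeR 0 genes passed for arsenic by phosphorus, arsenic by food, phosphorus by food and all 3 factors, and 738, 133, 658 and 944 stood at an unadjusted p under 0.05. DESeq2 called 18, 7, 46 and 95, and edgeR with every library counted called 10, 0, 175 and 307.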

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

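The tests of near-identical libraries and of cuticle genes were chosen after their results were seen, and the random assignments and splits before. No group held 4 or more units, so no unit was tested as standing apart, and no interaction passed its threshold in edgeR or in the limma score test.

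Near-identical libraries within groups: the pairs reached at most 3.45 times counting variance, against at least 12.4 for the others. Since the pairs were chosen by their low BCV, which fixes this gap, whether the same RNA was sequenced as 2 libraries stays open. Treatment alone as the source would make all same-group pairs alike, and 17 of 23 were not, with a BCV of at least 0.357. This argues against treatment alone, as far as the group labels are right. Some of the 17 involve libraries 1 and 14, whose labels are in doubt, and some share a near-identical library. Their median BCV of 0.648 cannot be weighed against the 0.604 of pairs across groups, since the closest same-group pairs were removed first. Libraries 43 and 50, near-identical across arsenic treatments, cannot be told apart as to which label is right: library 43 had a mean BCV of 0.569 to its own group and 0.524 to the other, and library 50 had 0.53 and 0.589. No biological explanation beyond treatment was tested.

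Genes called with every library counted: edgeR called 3727 over the 17 comparisons, against 0 with units. When the 15 units were assigned to groups at random with pairs kept together, 17 of 100 assignments, the real one included, called as many, with a median of 774 and a highest of 14497 in the others. Pairs counted as independent replicates may therefore account for the number of calls. The highest was several times the real count, and why was not tested.

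Cuticle genes lower under each single stressor: the control score exceeded the mean of the single-stressor groups by 2.62, and the widest gap between units of 1 group was 2.48, with a within-group SD of 1.08. The difference went beyond that gap, the bound set for excluding the state of the single control unit, by less than 1 SD, so this state and an effect of the stressors cannot be told apart with 1 control unit. The depth of library 46 is argued against as the only source for low food alone. The other unit there, library 36, scored -1.31, against 1.46 in the control. Library 46 scored -2.29, so it widens the difference of 2.62, which passed the gap of 2.48 only narrowly. Without library 46 the mean log2 fold change under low food alone was -4.33, against -3.25 with it. That mean was also lower without library 36, at -5.92, so its move does not weigh against library 46. With libraries 1 and 14 kept, the mean log2 fold change under arsenic alone was -0.26, against -2.05 without them. Groups with combined stressors differed from the control by -0.441 to -1.65, each within 2 standard errors, so a general effect of stress cannot be told apart from none. 

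Chance could not be excluded for the factor averages. As many genes at an unadjusted p under 0.05 came from 17 of 100 splits for low food (1287, highest other 2912), 22 of 100 for low phosphorus (1122, highest other 3787) and 94 of 100 for arsenic (209, highest other 2230). For each factor the highest other split exceeded the real count, and why was not tested.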

How the results depend on the processing

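Tests with every library counted, without library 46, without libraries 43 and 50 or with both as 1 unit, with each summed pair left out, with each unit left out of the list scores and with an additive fit were chosen after seeing the data. The count of called genes stayed at 0 in all 17 comparisons with median-ratio scaling, without a filter, with libraries 1 and 14 kept and without libraries 43 and 50. Median-ratio scaling moved the median log2 fold change of all genes by -0.11 for arsenic alone, -0.11 for low phosphorus alone, 0.13 for arsenic within low phosphorus and high food, 0.17 for arsenic by phosphorus and -0.14 for the 3-factor term, and turned no list called by camera. With an estimated correlation all 105 camera calls over the 17 comparisons were lost. For low food averaged without library 46, the exact permutation p was 0.0213 for DNA replication, 0.00866 for histones and 0.0160 for vitellogenins, each 0.213 after adjustment over 30 lists. Counts at an unadjusted p under 0.05 ran from 202 (without library 49) to 1667 (without the pair of 31 and 52) for arsenic within low phosphorus, from 117 (without libraries 43 and 50) to 736 (without library 36) within low food, and up to 160 (without library 43) within both. For arsenic by phosphorus they ran from 416 (without libraries 43 and 50) to 1499 and for all factors from 606 (without the pair of 37 and 51) to 1876, both highest without the pair of 31 and 52, and for arsenic by food up to 641 (without library 36). With libraries 1 and 14 kept, arsenic by phosphorus gave 354 and all factors 370. Library 46 held 200189 counts, so genes of low abundance were not measurable in it.

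DESeq2 called 25 genes for arsenic alone, 12 for low phosphorus alone, 18 for low food alone, 20 for low phosphorus with low food, 1 for arsenic with low phosphorus, 2 for arsenic with low food and 71 for all stressors. Within diets it called 12 for arsenic within low phosphorus, 30 within low food and 2 within both. For averages it called 12 (arsenic), 134 (low phosphorus) and 182 (low food), and for interactions 18 (arsenic by phosphorus), 7 (arsenic by food), 46 (phosphorus by food) and 95 (all factors). With every library counted, edgeR called 549 for arsenic alone, 85 for low phosphorus alone, 5 for low food alone, 702 for low phosphorus with low food, 87 for arsenic with low food, 603 for all stressors, 1 for arsenic within low phosphorus, 561 and 642 for low phosphorus and low food averaged, and 10, 175 and 307 for arsenic by phosphorus, phosphorus by food and all factors. DESeq2 made 73 false calls in simulated data of low food averaged where edgeR made 10. The additive fit called 6 genes for low food, and without library 46 edgeR called 1 for arsenic by phosphorus.

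The replicate numbers did not pair the libraries: 10 of 51 same-numbered pairs across groups had a correlation above 0.1, and 5 of 19 libraries matched their own number best. The replicate number as a block over those 19 libraries gave 418 genes for low phosphorus with low food, 318 for all stressors, 446 for low food averaged and 6 for phosphorus by food. The same libraries without the block gave 612, 457, 418 and 38, and also 124 for arsenic alone, 36 for low phosphorus alone, 53 for arsenic with low food, 83 for low phosphorus averaged, 7 for arsenic by phosphorus and 100 for all factors. The mean log2 fold change of DNA replication genes for arsenic within low phosphorus and high food was 0.39 with the block and -0.13 without it, and for arsenic by phosphorus 0.23 with the block and -0.06 without it. In the fit of units these means were -0.78 and -0.37. The fits over 19 libraries counted near-identical libraries separately, so they differ from the fit of units in more than the block. Libraries 33 and 48, of arsenic with low phosphorus, share replicate number 2. Without them that group keeps only library 28.

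The cause of each moved count was not tested, except that counting each library adds replicates. Leaving out 1 library or summed pair at a time, in 25 fits, gave 0 to 1 genes for low phosphorus averaged (1 without library 3), 0 to 2 for low food averaged (2 without library 48), 0 to 1 for arsenic by phosphorus (1 without library 46) and 0 for the other comparisons. A group left with 1 unit was assumed to vary like the others. With libraries 1 and 14 kept, the list means for arsenic alone were 0.60 for digestive peptidases, -0.10 for DNA replication and 0.66 for neural and eye markers, each with a changed camera direction. The camera direction of 7 further list results turned when 1 library was left out, and the ranges of their means over these fits follow. For arsenic within low food, mitochondrial ribosomal proteins ran from -1.26 to 0.882 and oxidative phosphorylation from -1.03 to 0.469, turning without library 3 (0.28 and 0.23). For arsenic within low phosphorus and low food, cytosolic ribosomal proteins ran from -0.0812 to 0.296 and neural and eye markers from -0.722 to 0.255, turning without library 34 (-0.0812 and -0.0146). Mitochondrial ribosomal proteins for arsenic with low phosphorus ran from -1.27 to -0.00378, turning without library 48. Immune genes for low phosphorus alone ran from -2.84 to -0.444 and muscle genes for arsenic within low phosphorus and high food from 0.252 to 1.27, turning without library 49. Camera compares a list with all other genes rather than with 0, so its direction can turn where a range keeps 1 sign. Why each direction turned was not tested.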

Other observations

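The limma scores and exact permutations of lists were chosen after seeing the data. Under low food, averaged over the other factors, 23 of 27 immune genes were higher. The immune list had a camera adjusted p of 0.0167, and 0.818 with an estimated correlation, and its score difference was 0.23 ± 0.33 (SE, limma adjusted p 0.836), or 0.02 without library 49, 0.04 without library 36, 0.36 without libraries 43 and 50, 0.43 without library 46 and 0.45 without the pair of 31 and 52. The member LOC124199931 (beta-1,3-glucan-binding protein-like), a recognition protein for microbial sugars, stood at a log2 fold change of 2.73 ± 0.63 (SE). LOC124192246 (serine protease easter-like) averaged 25.7 ± 18.4 CPM (SD, n = 9) under low food and 3.4 ± 1.59 CPM (SD, n = 6) under high food, and LOC124191916 (fatty acid-binding protein-like) 35.8 ± 22.4 against 10.6 ± 12.6 CPM. LOC124200142 (hemolymph clottable protein-like) averaged 129 ± 356 CPM (SD, n = 9) against 1560.0 ± 1590.0 CPM (SD, n = 6), with 1 low-food unit at 1080.0 CPM.

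Under low phosphorus averaged over the other factors, LOC124198803 (chitin deacetylase 7-like) stood at 203 ± 118 CPM (SD, n = 9) against 69.5 ± 102 CPM (SD, n = 6), and LOC124198118 (glutathione S-transferase Mu 1-like) at 24.6 ± 20.8 against 60.4 ± 29.7 CPM. Of 68 glutathione and thioredoxin genes 51 were lower, with a median log2 fold change of -0.23 and a camera adjusted p of 0.0136, and the adjusted p was 0.842 with an estimated correlation. Of 6 alkaline and acid phosphatase genes 4 were higher, with a score difference of 0.41 ± 0.32 (SE, limma adjusted p 0.672), or 0.19 without library 46 and 0.63 without library 36. For the 3-factor term, 11 of 13 genes of the list named arsenic methylation and efflux were negative, with a score difference of -2.04 ± 0.65 (SE, limma adjusted p 0.162).

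Libraries 1 and 14, labelled arsenic alone and left out of the comparisons except where they are said to be kept, held 2321535 and 1946469 counts, and LOC124194813 took 3.36% and 1.87% of them.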
